A study of Rattus norvegicus with 96 samples.

How the data were processed

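Liver RNA of 96 rats in 19 groups, as labelled, was measured on Agilent 1-colour (Cy3) Whole Rat Genome arrays, 1 array per rat, on 24 slides of 4 arrays scanned on 2 days. Per the labels' protocols the rats were male, got 1 dose by oral gavage, and gave total RNA with an integrity number above 8 that was labelled with Cy3. Acetaminophen (APAP) rats were fasted and refed after dosing, and carbon tetrachloride (CCl4) rats had feed throughout. The labels give dose and time but not the arm of each control, so controls whose title code starts with the letter A were inferred to be the APAP arm and those with B the CCl4 arm. Groups held 4 to 7 rats.

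The values of each array file are processed signal intensities, background-subtracted and multiplicatively detrended by Feature Extraction 10.7.3.1 per the file headers, on a linear scale and not scaled between arrays. The deposited table of intensities was checked against them and holds the same processed signal rounded to 3 significant digits (largest difference 0.50%), with array medians from 20.3 to 93.6. Each array holds 45018 spots, of which 43379 are not controls, for 41012 probes. No spot was saturated (0 in all), and 58 to 164 spots per array were marked as outliers by Feature Extraction and left out, so that 662 of the probe values (0.017%) were missing. By the quality marks in the file headers 60 arrays were in range and 36 were to be evaluated, and all 96 were kept. The 75th percentile of intensity was 179 to 544.7. An array has no sequencing depth, and rats per group, signal over background and scan day limit precision.

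Gene names came from the RefSeq table of the rat assembly GRCr8, used for names alone: 10735 probes were named by their accession, 9300 by their symbol, and 20977 kept the name in the file, which left 19942 probes with a symbol. Of 808 members of gene lists, 758 were on the array under their name and the others were not analysed.

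From the intensities, log2 values were computed and the 75th percentile of each array was subtracted. A probe was kept when well above background on at least 4 of 96 arrays (34253 probes), and for a gene with several kept probes (3911 genes) the brightest was used, which gave 29404 genes, 13903 of them with a symbol. Comparisons with control, between doses, between the effects of compounds and of times, and between the controls of both arms were fitted with limma 3.58.1 in R 4.3.3, each on its own groups, with moderated t tests. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and calls with a log2 change of at least 1 were counted as well. A fit of all 96 arrays with scan day as a term, the scan-day fit, was planned for comparisons with control and added for the others.

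33 gene lists were tested in the 12 comparisons with control with camera of limma at a preset correlation between genes of 0.01, and again with the correlation estimated from the arrays, adjusted over all 396 tests. Overlaps between compounds were tested with Fisher's exact test. Genes named in the text have a symbol, passed the test and have the largest changes: up to 10 higher and 10 lower for a high dose and up to 5 each for other comparisons. Each treated rat had to lie on the same side of the control mean (not asked of differences between effects), and the probe had to be well above background on every array of 1 group or more. Up to 4 members of each list were named as well, and 10 sentinel genes whatever they showed: Cyp2e1, Cyp7a1, Hmox1, Nqo1, Gdf15, Atf3, Cdkn1a, Ccnb1, A2m and Spp1. Where a group lacked signal well above background, the fold is given as a lower bound. Of 23 named results whose gene has several probes, 2 had probes of opposite sign, Abcb9 (−3.34 and 0.19) at 6 h and Sez6 (−3.27 and 0.15) at 3 d after CCl4 2000 mg/kg.

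The fits were tested on simulated data for 28893 genes, 100 of them changed at each size. Without a scan day and at a log2 size of 1 the own-group fit recovered 20% for APAP 1250 mg/kg at 6 h, 35% at 3 d and 26% for CCl4 2000 mg/kg at 24 h, and 16% for the difference between the CCl4 effects at 24 h and 6 h; at a size of 2 it recovered 77%, 74%, 73% and 55%. With a simulated scan day the own-group fit recovered 9% and 64% for CCl4 2000 mg/kg at 24 h (0 false calls; scan-day fit 48% and 90%, 8 false) and 23% and 61% at 3 d (22 false). That of APAP at 3 d made 8685 false calls, and the scan-day fit made 7 and recovered 49% and 86%. For CCl4 at 3 d the scan-day fit recovered 56% and 85% (11 false). In the CCl4 24 h simulation, camera found 5 of 5 shifted lists of 33 and 0 false ones at both correlations. It cannot decide between them, since on the arrays 1 of 172 preset calls held at the estimate.

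The alternatives tried were quantile normalization, normexp background correction (offset 50) with quantile normalization, a percentile over the 18433 probes well above background on all arrays, the unscaled deposited table, no filter (35537 genes), a filter on at least 48 of the arrays (23077 genes), the mean of a gene's probes, all arrays in 1 fit, array weights, blocks for slide, slide position and scan day, and leaving out each array in turn. Other splits of the rats into groups of the same sizes were counted with fixed seeds, and the highest and lowest array of each group was tested with Dixon's test. Pairs of arrays were compared by the median absolute deviation of their differences over 15276 genes well above background on all arrays, and by genes with 2 clear levels, with a gap of at least 1 on the log2 scale, at least 10 arrays on either side and both levels in 10 or more of 19 groups (11 genes). This gap was lowered to 0.5 (27 genes) before any pair was seen and put back to 1 after, and both are reported. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and statmod 1.5.0 were used besides. No array was left out of the values in the report, and some results that meet the naming rule are not reported here.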

Results

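Gene expression was measured in livers of male Sprague-Dawley rats, 96 by the labels and each on its own array, after a single oral dose of acetaminophen (APAP), an analgesic that injures the liver in overdose, or of carbon tetrachloride (CCl4), a solvent used as a model liver toxicant. The APAP arm held 4 control rats at each of 6 h, 24 h, 3 d and 7 d, 5 rats given 100 mg/kg at each of 6 h and 24 h, and 5, 7, 7 and 7 rats given 1250 mg/kg at 6 h, 24 h, 3 d and 7 d. The CCl4 arm held 4, 5 and 5 control rats at 6 h, 24 h and 3 d, and 5 rats given 50 mg/kg and 5 given 2000 mg/kg at each of these times. APAP-arm rats had been fasted overnight before dosing and got feed back 4 h after it, and CCl4-arm rats had feed throughout. Each array carried 41012 probes other than controls, of which 51.1% to 81.1% (median 66.8%) were well above background. Values are log2 intensities relative to the array's 75th percentile, changes are log2 differences with the standard error from limma, and 29404 genes were tested. The median Pearson correlation across probes between arrays of one group lay between 0.948 and 0.981, and that over all pairs of arrays was 0.963.

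The arrays had been scanned on 2 days, 48 on each, and the days were shared unevenly among the groups. The first principal component held 41.1% of the variance and followed the day: arrays of day 1 lay between −60.8 and 145, and those of day 2 between −131 and 19.2. Dim probes read lower on day 2, with a median difference of −0.87, −0.98 and −0.77 in the dimmest of 10 bins of brightness and of 0.11 and 0.09 in the brightest. Each comparison is therefore given from its own groups and also from a fit of all 96 arrays with scan day as a term, called the scan-day fit. This fit was planned for comparisons with control and added for others after the day was seen to matter.

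**Figure D1:**
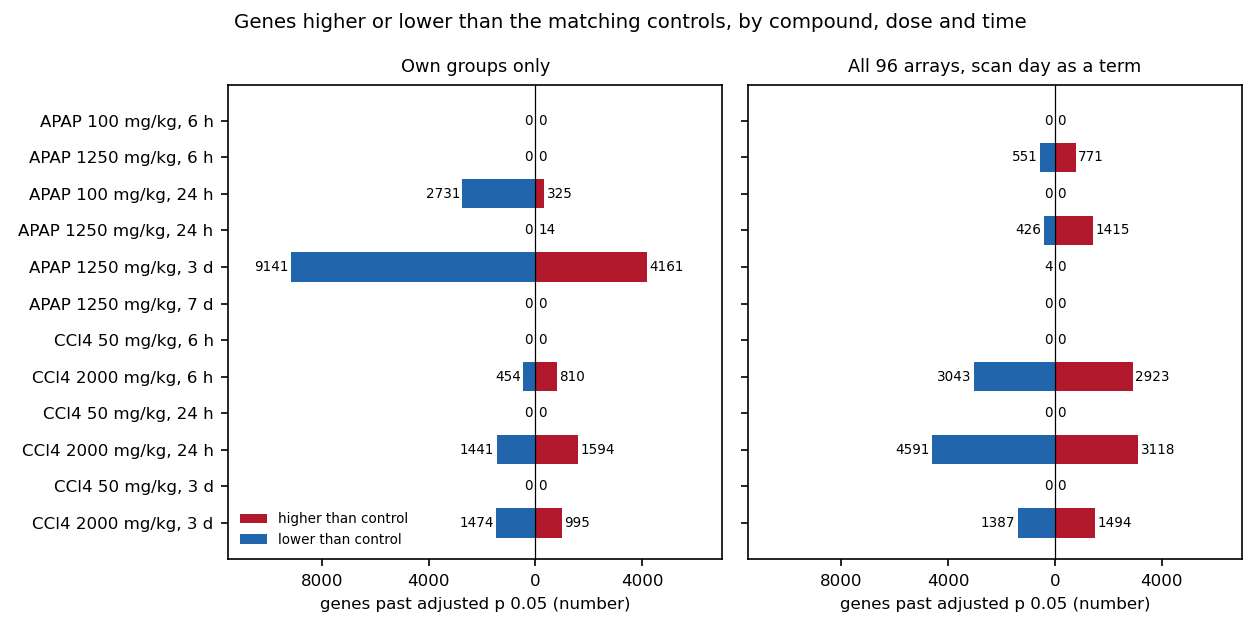
Number of genes higher and lower at an adjusted p under 0.05 in each comparison with control, from the comparison's own groups and from the scan-day fit. APAP 1250 mg/kg at 3 d goes from 4161 higher and 9141 lower to 0 and 4 with scan day in the fit, while CCl4 2000 mg/kg at 24 h goes from 1594 and 1441 to 3118 and 4591.

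To learn what the high dose of CCl4 did within hours, 5 rats at 6 h after 2000 mg/kg were compared with 4 controls. Hspa1a, an inducible chaperone, rose most, by 6.89 ± 0.76 (adjusted p = 0.0071). Atf3, a stress-responsive transcription factor, rose by 6.36 ± 0.49 (82-fold, adjusted p = 0.0031) and Fosl1, an AP-1 subunit, by 6.15 ± 1.35. The chemokines Ccl12, Ccl2 and Cxcl10 rose by 5.89 ± 0.88, 5.47 ± 0.68 and 5.12 ± 0.46, and Trib3 and the hepatokine Fgf21 by 5.03 ± 0.42 and 4.86 ± 0.57. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 7.96 ± 0.80 (adjusted p = 0.0051) from a control mean of 3.85 to −4.11, where 2 of 5 treated arrays read it well above background. Bcl6, a transcriptional repressor (−3.37 ± 0.42), the transporter Abcb9 (−3.34 ± 0.57, and 0.19 on its other probe) and Klf12 (−2.86 ± 0.59) fell too. For each of these genes, 5 of 5 treated rats lay on the same side of the control mean.

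Among gene lists fixed before the data were examined, ribosome biogenesis rose in 18 of 27 members, led by Nop58 (2.12 ± 0.33), Nop56 (1.89 ± 0.43) and Ftsj3 (1.80 ± 0.18). Its median was 1.04 (scan-day fit 1.02, within days 1.11 and 1.05), with adjusted p = 7.3e-21, and adjusted p = 0.49 with an estimated correlation. The proteasome rose in 14 of 31 members, led by Psma5 (1.23 ± 0.19) and Psmd12 (1.18 ± 0.20). The median was 0.71 (scan-day fit 0.70, within days 0.95 and 0.64), with adjusted p = 1.5e-20, and adjusted p = 0.48 with an estimated correlation. The integrated stress and unfolded protein response rose in 13 of 20 members, among them Atf3 (6.36 ± 0.49), Trib3 (5.03 ± 0.42), Fgf21 (4.86 ± 0.57) and Ppp1r15a (3.03 ± 0.53). Its median was 1.82 (scan-day fit 1.82, within days 1.69 and 1.87), with adjusted p = 2.5e-17, and adjusted p = 0.47 with an estimated correlation. Cytokines, chemokines and adhesion genes rose in 13 of 20 members, among them Ccl2 (5.47 ± 0.68), Cxcl10 (5.12 ± 0.46) and Cxcl1 (4.68 ± 0.69). The median was 1.99 (scan-day fit 2.11, within days 2.01 and 2.14), with adjusted p = 1.1e-13, and adjusted p = 0.49 with an estimated correlation. The heat shock response rose in 11 of 18 members, Hspa1a (6.89 ± 0.76), Hspb1 (3.44 ± 0.54) and Bag3 (2.92 ± 0.51) first. Its median was 1.64 (scan-day fit 1.62, within days 1.68 and 1.47), with adjusted p = 5.8e-13, and adjusted p = 0.49 with an estimated correlation. Immediate early genes rose in 8 of 19 members, among them Fosl1 (6.15 ± 1.35). The median was 2.17 (scan-day fit 2.09, within days 1.72 and 1.94), with adjusted p = 2.5e-11, and adjusted p = 0.49 with an estimated correlation. The NRF2 and antioxidant response, which neutralises electrophiles, rose in 5 of 24 members, Hmox1 (2.99 ± 0.67), Txnrd1 (2.29 ± 0.48) and Osgin1 (2.17 ± 0.36) leading. Its median was 0.69 (scan-day fit 0.69, within days 0.66 and 0.62), with adjusted p = 0.00015, and adjusted p = 0.49 with an estimated correlation. Genes of the pericentral zone, where CCl4 is activated by Cyp2e1, fell in 6 of 20 members, namely in Cyp7a1 (−7.96 ± 0.80), Glul (−2.14 ± 0.49), Slc1a2 (−1.91 ± 0.28) and Oat (−1.68 ± 0.39) and other members. The median was −0.98 (scan-day fit −0.98, within days −0.73 and −1.12), with adjusted p = 1.9e-09, and adjusted p = 0.49 with an estimated correlation. Bile acid synthesis and transport fell in 5 of 24 members, with Cyp7a1 (−7.96 ± 0.80), Nr0b2 (−2.31 ± 0.37), Baat (−1.5 ± 0.34) and Cyp8b1 (−1.44 ± 0.33) lowest. Its median was −0.69 (scan-day fit −0.74, within days −0.58 and −0.85), with adjusted p = 1.1e-06, and adjusted p = 0.51 with an estimated correlation. Cholesterol synthesis fell in 4 of 25 members, with Hmgcs1 (−2.18 ± 0.43) and Msmo1 (−1.86 ± 0.31) lowest. The median was −0.72 (scan-day fit −0.74, within days −0.90 and −0.54), with adjusted p = 6.5e-07, and adjusted p = 0.51 with an estimated correlation. Cyp2e1 itself stood at −1.06 ± 0.37 and did not pass the test (adjusted p = 0.14), while it fell by 1.09 ± 0.35 in the scan-day fit (adjusted p = 0.017).

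In limma, 810 genes were higher and 454 lower at 6 h, 587 and 346 of them by a log2 change of at least 1, and the scan-day fit gave 2923 and 3043. The changes of all genes had a correlation of 0.476 between the scan days, and within them limma called 0 on day 1 (2 treated and 2 control rats, 4773 at an unadjusted p under 0.05) and 0 on day 2 (3 and 2 rats, 4606). The unscaled deposited values moved the median of all genes from −0.04 to 0.34 and gave 1483 higher and 87 lower. The count was 340, 251, 66 or 406 without control replicate 1, 2, 3 or 4 and 359, 579 or 793 without treated replicate 1, 2 or 3.

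At 24 h after 2000 mg/kg CCl4 (5 rats against 5 controls) the question was what the liver expressed a day later. Spp1, the matrix protein osteopontin, rose by 7.54 ± 0.79 (187-fold, adjusted p = 0.0009) and Lcn2, an iron-binding acute phase protein, by 6.64 ± 1.48 (adjusted p = 0.023). The leukocyte receptor Lilrb4 rose at least 30.5-fold (adjusted p = 0.00043), since it was not well above background on any of the 5 control arrays. Slpi, a protease inhibitor, Gpnmb, a macrophage glycoprotein, and Ccl2 rose by 5.65 ± 0.55, 5.62 ± 0.62 and 5.5 ± 1.01. Stac3 (−5.41 ± 0.75), the carbonic anhydrase Car3 (−5.23 ± 0.83), the flavin monooxygenase Fmo1 (−4.33 ± 0.83) and Nrep (−3.41 ± 0.71) fell most. Cyp2e1, the P450 that activates both compounds, fell by 2.0 ± 0.54 (adjusted p = 0.043), and 5 of 5 treated rats lay on the same side of the control mean for each gene named.

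Macrophage and monocyte markers rose in 13 of 22 members, with Gpnmb (5.62 ± 0.62), Mmp12 (4.55 ± 0.76), Lyz2 (4.40 ± 0.29) and Itgam (4.19 ± 0.73) in front. Its median was 1.18 (scan-day fit 1.18, within days 1.22 and 1.16), with adjusted p = 4.3e-14, and adjusted p = 0.48 with an estimated correlation. T, B and NK lymphocyte markers rose in 10 of 18 members, such as Cd8a (2.37 ± 0.30) and Cd8b (1.90 ± 0.34). The median was 1.12 (scan-day fit 1.12, within days 1.40 and 0.96), with adjusted p = 2.8e-10, and adjusted p = 0.47 with an estimated correlation. S phase and DNA replication genes rose in 14 of 27 members, the replication helicase subunits and E2f1 in front with Mcm3 (2.41 ± 0.20), Mcm5 (2.13 ± 0.32), Mcm6 (2.0 ± 0.24) and E2f1 (1.99 ± 0.22). Its median was 0.70 (scan-day fit 0.70, within days 0.97 and 0.79), with adjusted p = 4.3e-14, and adjusted p = 0.47 with an estimated correlation. Mitosis genes rose in 6 and fell in 1 of 29, Ccna2 (1.71 ± 0.31) and Mki67 (1.54 ± 0.32) being highest. The median was 0.60 (scan-day fit 0.60, within days 1.10 and 0.29), with adjusted p = 2.3e-06, and adjusted p = 0.58 with an estimated correlation. The integrated stress and unfolded protein response rose in 12 of 20 members. Its median was 1.10 (scan-day fit 1.10, within days 1.37 and 0.96), with adjusted p = 4.6e-12, and adjusted p = 0.47 with an estimated correlation. Interferon-stimulated genes rose in 6 of 20 members. The median was 0.58 (scan-day fit 0.58, within days 0.75 and 0.55), with adjusted p = 7.1e-07, and adjusted p = 0.51 with an estimated correlation. Plasma proteins of the hepatocyte fell in 25 of 39 members, with Serpina6 (−2.04 ± 0.49), Apoa2 (−1.73 ± 0.34) and F11 (−1.62 ± 0.38) lowest. Its median was −0.76 (scan-day fit −0.76, within days −0.93 and −0.61), with adjusted p = 4.7e-09, and adjusted p = 0.58 with an estimated correlation. The urea cycle and amino acid breakdown fell in 12 of 32 members, with Otc (−2.28 ± 0.44), Gnmt (−1.68 ± 0.44) and Cth (−1.59 ± 0.36) lowest. The median was −0.93 (scan-day fit −0.93, within days −1.27 and −0.69), with adjusted p = 1.4e-05, and adjusted p = 0.65 with an estimated correlation. Drug-metabolising P450 fell in 10 of 26 members, with Cyp3a2 (−2.68 ± 0.59), Cyp2c11 (−2.66 ± 0.61) and Cyp2e1 (−2.0 ± 0.54) lowest. Its median was −0.88 (scan-day fit −0.88, within days −1.22 and −0.70), with adjusted p = 0.0003, and adjusted p = 0.61 with an estimated correlation. Cyp1a1 rose by 2.78 ± 0.48. Conjugation and phase II enzymes fell in 11 of 30 members, with Ugt2b1 (−2.71 ± 0.25) and Gstm7 (−2.56 ± 0.52) lowest. The median was −0.77 (scan-day fit −0.77, within days −0.96 and −0.66), with adjusted p = 4.1e-05, and adjusted p = 0.58 with an estimated correlation. The acute phase list, with 7 members higher and 2 lower of 23 and a median of −0.13 (0.19 after quantile normalization and after normexp, 0.34 unscaled), had no call (adjusted p = 0.18), although Lcn2, Orm1 (2.87 ± 0.45) and Il1rn (2.78 ± 0.53) rose; its mean and its test pointed up.

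The limma count was 1594 higher and 1441 lower, 1083 and 802 by at least 1 on the log2 scale, against 3118 and 4591 in the scan-day fit. The changes had a correlation of 0.492 between the days. Within day 2 limma called 831 and 1692 (3 rats per group), and within day 1 it called 0 (2 per group, 4046 at an unadjusted p under 0.05). The median of all genes was −0.23 (−0.07 after quantile normalization, −0.02 after normexp and 0.25 unscaled), and unscaled values gave 5161 higher and 206 lower. The count was 1909, 1785, 1567, 2005 or 1380 without control replicate 1, 2, 3, 4 or 5 and 1457 or 1795 without treated replicate 1 or 2.

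**Figure D2:**
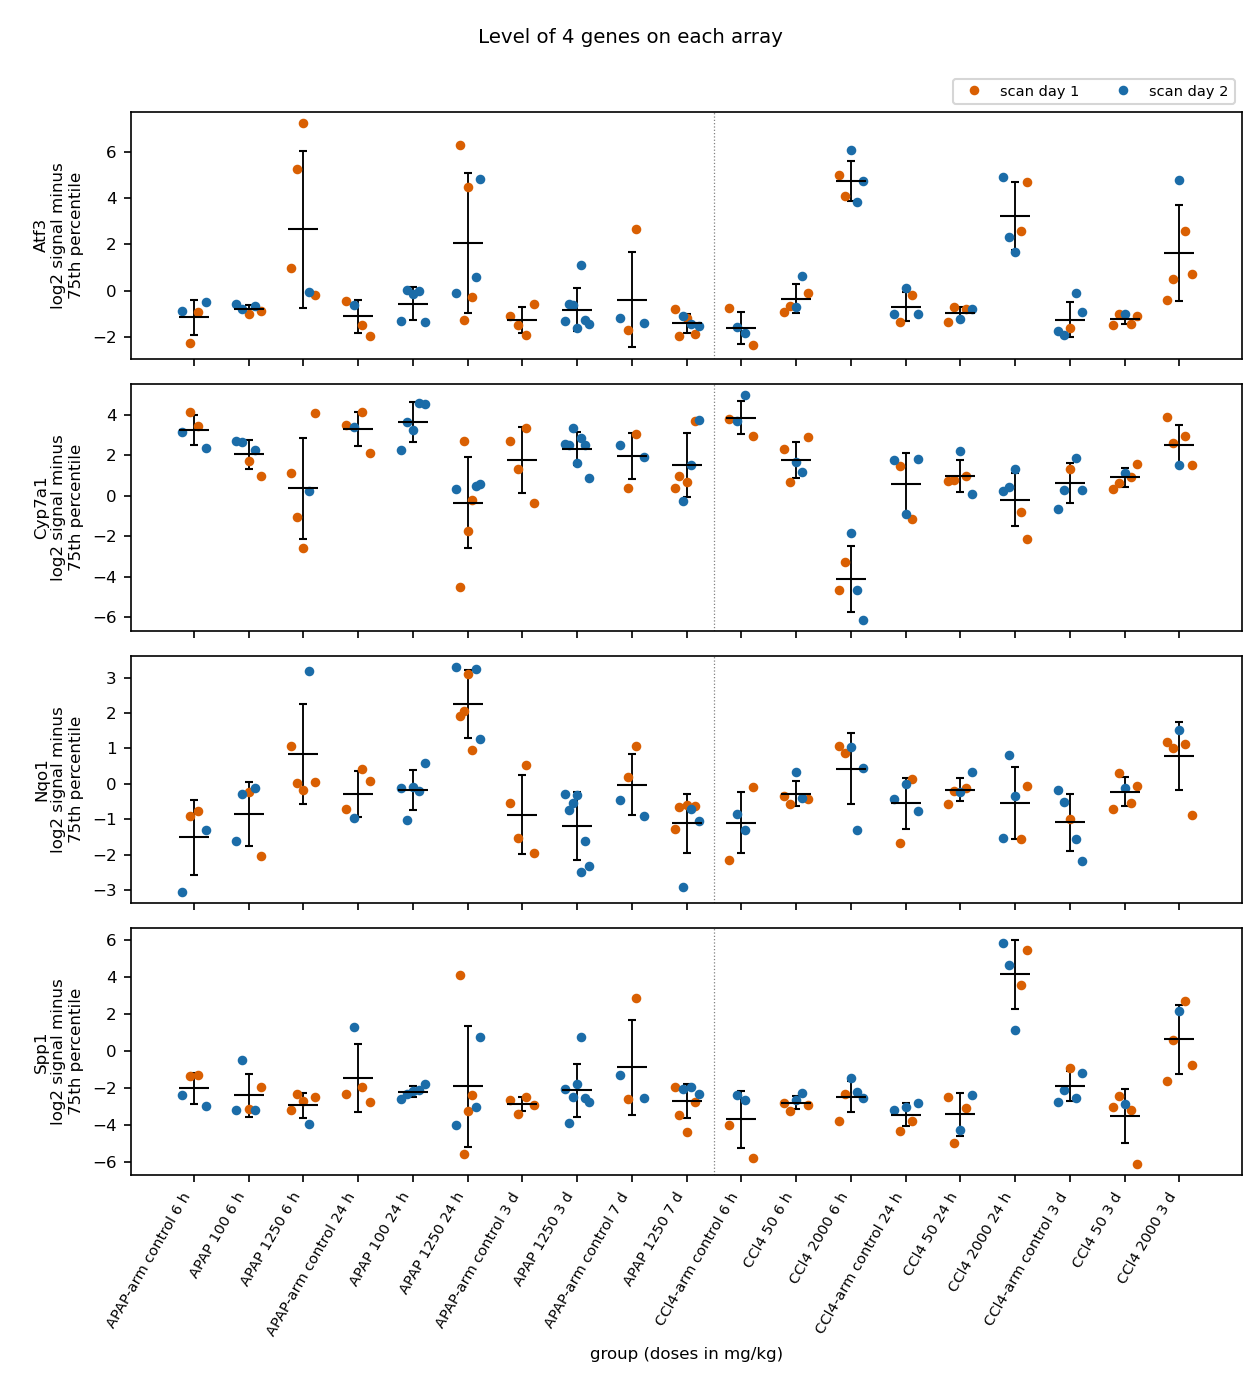
Level of Atf3, Cyp7a1, Nqo1 and Spp1 on each of the 96 arrays (vertical axis: log2 intensity relative to the array's 75th percentile; bars: group mean ± SD; colour: scan day). Against their controls, Atf3 was higher by 6.36 at 6 h and Spp1 by 7.54 at 24 h after CCl4 2000 mg/kg.

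At 3 d after 2000 mg/kg CCl4 (5 rats against 5 controls) the question was which changes lasted. Trem2, a lipid-sensing macrophage receptor, rose by 4.81 ± 0.61 (adjusted p = 0.005; scan-day fit 4.45 ± 0.72), Lilrb4 by 4.23 ± 0.64 (4.0 ± 0.79) and Gpnmb by 3.89 ± 0.63 (3.98 ± 0.72). Trib3 and the metalloelastase Mmp12 rose by 3.64 ± 0.72 and 3.61 ± 0.70, Cthrc1, a secreted collagen regulator, by 3.32 ± 0.73 and Fgf21 by 3.29 ± 0.35. Stac3 fell by 8.98 ± 1.18 (adjusted p = 0.0053, scan-day fit −8.90 ± 1.35). The carboxylesterase Ces1d (−5.16 ± 0.66), the leukotriene synthase Ltc4s (−4.89 ± 0.78) and Ces1dl1 (−4.63 ± 0.49) fell too. For each of these genes 5 of 5 treated rats lay on one side of the control mean, and the scan-day fit kept every call.

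Macrophage and monocyte markers rose in 9 of 22 members, with Gpnmb (3.89 ± 0.63), Mmp12 (3.61 ± 0.70) and Tyrobp (1.19 ± 0.28) highest. Its median was 0.82 (scan-day fit 0.80, within days 0.62 and 1.19), with adjusted p = 1.3e-07, and adjusted p = 0.58 with an estimated correlation. The integrated stress and unfolded protein response rose in 7 of 20 members. The median was 0.80 (scan-day fit 0.90, within days 0.44 and 1.28), with adjusted p = 4.8e-06, and adjusted p = 0.54 with an estimated correlation. The NRF2 and antioxidant response rose in 8 of 24 members, among them Akr7a3 (1.82 ± 0.27), Abcc3 (1.68 ± 0.44) and Cbr1 (1.28 ± 0.17). Its median was 0.41 (scan-day fit 0.38, within days 0.53 and 0.53), with adjusted p = 0.0034, and adjusted p = 0.5 with an estimated correlation. The urea cycle and amino acid breakdown fell in 14 of 32 members, led by Oat (−2.24 ± 0.20) and Gnmt (−2.09 ± 0.36). The median was −0.53 (scan-day fit −0.54, within days −0.87 and −0.59), with adjusted p = 1.1e-11, and adjusted p = 0.49 with an estimated correlation. Plasma proteins of the hepatocyte fell in 11 of 39 members, with F11 (−1.73 ± 0.24) and Apoc3 (−1.36 ± 0.24) lowest. Its median was −0.56 (scan-day fit −0.51, within days −0.50 and −0.66), with adjusted p = 8.4e-11, and adjusted p = 0.52 with an estimated correlation. Drug-metabolising P450 fell in 7 of 26 members, with Cyp3a9 (−2.40 ± 0.55) and Cyp3a2 (−2.15 ± 0.18) lowest. The median was −0.45 (scan-day fit −0.36, within days −0.45 and −0.66), with adjusted p = 0.001, and adjusted p = 0.58 with an estimated correlation. Cyp1a1 rose by 3.16 ± 0.47. Red blood cell markers fell in 4 of 8 members, namely Hbb (−2.64 ± 0.38), Alas2 (−2.63 ± 0.51), Hbb-b1 (−2.33 ± 0.21) and Ahsp (−1.85 ± 0.45). Its median was −1.73 (scan-day fit −1.93, within days −1.06 and −2.25), with adjusted p = 0.0001, and adjusted p = 0.5 with an estimated correlation. Alas2 was lower in 4 of 5 rats. Stellate cell, myofibroblast and matrix genes, which lay down scar tissue, rose in 3 and fell in 2 of 23. The median was 0.50 (scan-day fit 0.34, within days 0.03 and 0.37), with adjusted p = 0.015, and adjusted p = 0.71 with an estimated correlation. S phase and mitosis genes had no call (adjusted p = 0.39 and 0.78). Their medians differed in sign between the days, at 0.47 and −0.49 and at 1.14 and −0.86.

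The limma count was 995 higher and 1474 lower, 420 and 483 by at least 1, and 1494 and 1387 in the scan-day fit, which shared 1514 genes. Scan days were uneven here, with 4 treated and 1 control rats on day 1 and 1 and 4 on day 2, too few for a test within days. The changes of all genes had a correlation of 0.0584 between them. The unscaled deposited values gave 272 higher and 92 lower, with the median of all genes at 0.35 in place of 0.09. The count was 967, 799, 1200 or 961 without control replicate 1, 2, 4 or 5 and 1404, 5419, 947 or 1551 without treated replicate 2, 3, 4 or 5.

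**Figure D3:**
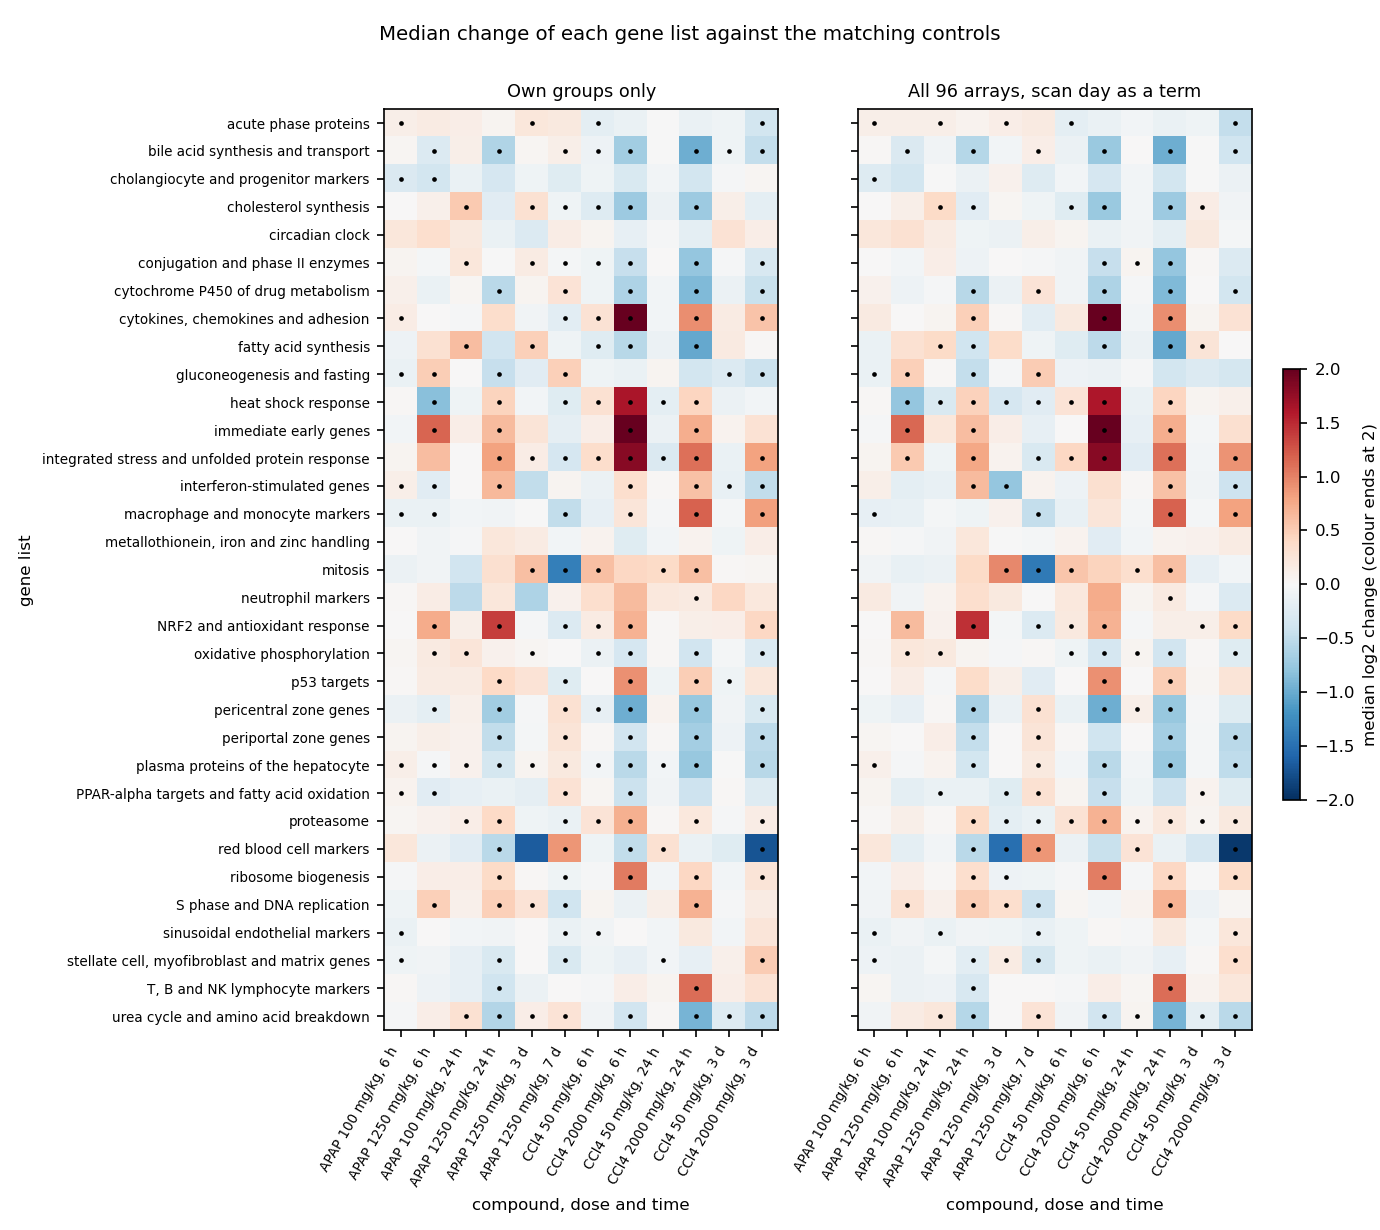
Median log2 change of each of 33 gene lists in the 12 comparisons with control (colour), from each comparison's own groups, with a dot where the list passed an adjusted p under 0.05 at the preset correlation. At CCl4 2000 mg/kg and 24 h macrophage and monocyte markers stand at 1.18 and plasma proteins at −0.76.

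The low dose of CCl4, 50 mg/kg, was compared with control in 5 rats per time. The sentinel genes gave no call at 6 h: Atf3 stood at 1.26 ± 0.40, Cyp7a1 at −2.11 ± 0.52 and Nqo1 at 0.81 ± 0.39 (0.46 ± 0.32 without control replicate 1), each with an adjusted p of 1 and with 5 of 5 rats on that side of the control mean. At 24 h Spp1 stood at 0.00 ± 0.52 and Cyp2e1 at −0.09 ± 0.17, and at 3 d Spp1 stood at −1.61 ± 0.67 (adjusted p = 0.44, and −0.97 ± 0.39 without treated replicate 5) and Cdkn1a, a cell cycle inhibitor, at −1.0 ± 0.44. With limma 0 genes passed at 6 h, 24 h and 3 d, in the scan-day fit too, against 613, 604 and 3251 at an unadjusted p under 0.05. The count was 2615 at 3 d without treated replicate 3 and 3 at 6 h without treated replicate 1. At the preset correlation gene lists were still called, 6, 2 and 0 higher and 9, 4 and 5 lower. With 0 genes too, APAP 100 mg/kg at 6 h had 5 and 5, and APAP 1250 mg/kg at 7 d 9 and 14. CCl4 2000 mg/kg at 24 h had 13 and 10.

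The doses of CCl4 were compared to see what 2000 mg/kg added to 50 mg/kg. At 6 h Hspa1a was higher at 2000 mg/kg by 6.16 ± 0.67 (adjusted p = 0.017), Fosl1 by 5.49 ± 1.24 and Mmp3, a matrix metalloproteinase not well above background in any low-dose rat, at least 21.4-fold. Cyp7a1 differed by −5.85 ± 0.75 and Nr0b2, a repressor of bile acid synthesis, by −2.55 ± 0.44. At 24 h Spp1, Gpnmb and Lcn2 were higher by 7.54 ± 0.87, 6.15 ± 0.39 and 6.07 ± 1.45, and Stac3, Car3 and Fmo1 differed by −5.46 ± 0.78, −5.34 ± 0.83 and −4.5 ± 0.82. At 3 d Trem2 was higher by 4.43 ± 0.67 and Lilrb4, not well above background in any low-dose rat, at least 9.7-fold, and Stac3 and Ltc4s differed by −8.58 ± 1.15 and −4.81 ± 0.85. In all of these, 5 of 5 high-dose rats lay on one side of the low-dose mean. The limma counts were 656 higher and 304 lower at 6 h, 1603 and 1205 at 24 h and 90 and 80 at 3 d, and the scan-day fit gave 2679 and 2439, 3078 and 3755, and 1283 and 829. Unscaled values gave 3341 and 25, 4775 and 217, and 23 and 12, and at 6 h normexp gave 1229 and 881 and the percentile over bright probes 650 and 481. The count at 6 h was 258, 0, 325 or 3 without low-dose replicate 1, 2, 3 or 5 and 2, 334, 433 or 633 without high-dose replicate 1, 2, 3 or 5. At 24 h it was 1461, 1298, 1312 or 1849 without low-dose replicate 1, 2, 4 or 5 and 1366 or 1591 without high-dose replicate 1 or 2, and at 3 d 36, 17, 33, 22 or 30 without low-dose replicate 1, 2, 3, 4 or 5 and 112, 99, 68, 29 or 41 without high-dose replicate 1, 2, 3, 4 or 5.

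To ask what the high dose of APAP did early, 5 rats at 6 h after 1250 mg/kg were compared with 4 controls. From these groups alone limma called 0 genes (2304 at an unadjusted p under 0.05), so the genes here are those called in the scan-day fit, by the same naming rule applied after the scan days had been seen. Atf3 rose by 3.80 ± 0.97 (adjusted p = 0.01; own groups 3.79 ± 1.5, adjusted p = 0.59), Ddit4l, an inhibitor of mTOR signalling, by 3.66 ± 0.54, Chac1, which degrades glutathione, by 3.11 ± 0.65 and Trib3 by 3.0 ± 0.67. Nqo1, an NRF2-driven quinone reductase, rose by 2.36 ± 0.58 (adjusted p = 0.0079), and Hmox1 by 1.85 ± 0.57 with 3 of 5 rats above the control mean. The phosphate transporter Slc34a2 (−2.84 ± 0.66), the adenosine receptor Adora2b (−2.36 ± 0.62) and the clock gene Per2 (−2.25 ± 0.50) fell. Apart from Hmox1, 5 of 5 treated rats lay on one side of the control mean for these genes. Replicates 1, 2 and 3, which shared a slide, read Atf3 at 1.0, 5.26 and 7.25 and Hmox1 at 5.09, 5.90 and 6.61, against −0.07 and −0.20 for Atf3 and 2.08 and 1.78 for Hmox1 in replicates 4 and 5. Nqo1 was highest in replicate 4 (3.20), and without it the own-group change was 1.75 ± 0.52. Replicate 4, the one treated array of day 2, lay closer to replicate 1 of APAP at 24 h (Nqo1 3.29) than any pair within a group, so its time point and the medians of day 2 below are in doubt.

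The heat shock response lay lower as a list after APAP at 6 h. Its median was −0.83 (scan-day fit −0.78, within days −0.84 and −0.76), with adjusted p = 1.3e-12, and adjusted p = 0.48 with an estimated correlation. In the scan-day fit it fell in 8 of 18 members, Hsp90aa1 (−1.35 ± 0.32), Fkbp4 (−1.25 ± 0.20), Hsph1 (−1.21 ± 0.37) and Hsp90ab1 (−1.12 ± 0.25) leading, and 9 fell in the own-group fit adjusted over the list alone, against 0 over all genes tested. Its controls read Hspa1a higher than those of the CCl4 arm (scan-day fit 4.73 ± 1.26). The NRF2 and antioxidant response lay higher, and 11 of 24 rose in the scan-day fit. The median was 0.74 (scan-day fit 0.64, within days 0.46 and 1.48), with adjusted p = 2.0e-05, and adjusted p = 0.5 with an estimated correlation. Of S phase genes, 4 of 27 rose in the scan-day fit, among them Ccne1 (2.28 ± 0.46). Its median was 0.48 (scan-day fit 0.30, within days 0.04 and 1.08), with adjusted p = 0.0002, and adjusted p = 0.51 with an estimated correlation. Immediate early genes had a call, with medians of unlike sign in the days. The median was 1.17 (scan-day fit 1.15, within days 1.43 and −0.37), with adjusted p = 0.00022, and adjusted p = 0.6 with an estimated correlation. The scan-day fit called 771 genes higher and 551 lower (158 and 182 by at least 1), the changes of all genes had a correlation of −0.0875 between the days, and own groups with scan day added gave 0 in limma (2408 at an unadjusted p under 0.05). Within day 1 limma called 0 (4 treated and 2 control rats, 2829 at an unadjusted p under 0.05), and day 2 held 1 treated rat. Other groupings of the rats within scan days gave as many genes as the scan-day fit in 3 of 45 cases with the real one, so chance was not excluded for this count. Without treated replicate 4 the own-group count was 1.

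At 24 h after 1250 mg/kg APAP (7 rats against 4 controls) the question was what followed a day after dosing. Treated replicate 1 and control replicates 2 and 4 are in close pairs with other groups (last paragraph), so their labels are in doubt. Ugt2b7, a glucuronidating enzyme, rose by 6.65 ± 0.48 (100-fold, adjusted p = 0.00027), Akr7a3, an aldehyde reductase, by 4.55 ± 0.32, the export pump Abcc3 by 2.92 ± 0.23 and Ugt1a6 by 2.87 ± 0.27. The transporter Slc17a3, the epoxide hydrolase Ephx1, the glutathione reductase Gsr and Ugdh, which makes UDP-glucuronate, rose by 2.22 ± 0.31, 2.21 ± 0.29, 1.77 ± 0.22 and 1.53 ± 0.21, all in 7 of 7 rats. In the scan-day fit Ddit4l also rose, by 5.11 ± 0.50 (own groups adjusted p = 0.052), Phgdh, the entry enzyme of serine synthesis, by 3.47 ± 0.53, Asns by 2.73 ± 0.38 and Nqo1 by 2.54 ± 0.54 (own groups adjusted p = 0.15). Stac3 (−4.42 ± 1.31) and Cyp7a1 (−3.69 ± 0.83) fell there (own groups adjusted p = 0.53 and 0.3).

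The NRF2 and antioxidant response rose in 5 of 24 with a median of 1.39 (scan-day fit 1.46, within days 1.63 and 1.16), in 14 adjusted over the list alone and in 17 in the scan-day fit, with Akr7a3 (4.53 ± 0.43), Abcc3 (2.88 ± 0.36) and Nqo1 (2.54 ± 0.54) there. This list had adjusted p = 7.9e-22, and adjusted p = 0.034 with an estimated correlation (8e-06 in the scan-day fit), the one call among 172 that held with an estimated correlation. The proteasome rose in 17 of 31 members in the scan-day fit. Its median was 0.40 (scan-day fit 0.39, within days 0.40 and 0.29), with adjusted p = 4.6e-12, and adjusted p = 0.5 with an estimated correlation. The integrated stress and unfolded protein response rose in 9 of 20 in that fit, Trib3 (3.20 ± 0.62) and Atf3 (3.18 ± 0.90) in 6 of 7 rats, Atf3 reading 6.29, 4.48 and 4.81 in replicates 2, 4 and 7 and at most 0.58 in the others. The median was 0.81 (scan-day fit 0.78, within days 1.01 and 0.54), with adjusted p = 2.0e-07, and adjusted p = 0.48 with an estimated correlation. Pericentral zone genes fell in 8 of 20 in that fit, with Cyp7a1 (−3.69 ± 0.83), Oat (−2.17 ± 0.42), Glul (−2.14 ± 0.33) and Cyp1a2 (−1.97 ± 0.45) lowest. Its median was −0.69 (scan-day fit −0.65, within days −0.66 and −0.57), with adjusted p = 2.5e-05, and adjusted p = 0.58 with an estimated correlation. Of the urea cycle and amino acid breakdown, 10 of 32 fell in that fit. The median was −0.58 (scan-day fit −0.57, within days −0.77 and −0.32), with adjusted p = 1.1e-07, and adjusted p = 0.58 with an estimated correlation. Cyp2e1 stood at −0.02 ± 0.43 and Spp1 at −0.47 ± 1.60, neither past the test (adjusted p = 0.99 and 0.93). The limma count was 14 higher and 0 lower (2398 at an unadjusted p under 0.05), 22 and 3 after normexp, 26 and 0 with scan day added to the own groups and 1415 and 426 in the scan-day fit. Between the days the changes of all genes had a correlation of 0.238. Within day 1 it was 2 and 0 (4 treated and 3 control rats), and day 2 held 1 control. Regrouping the rats within days gave as many genes as the scan-day fit in 6 of 100 draws with the real one, so chance was not excluded for that count. The count of 14 was 6, 8, 5 or 7 without control replicate 1, 2, 3 or 4 and 6, 5 or 6 without treated replicate 4, 5 or 6.

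At 3 d after 1250 mg/kg APAP all 7 treated rats had been scanned on day 2 and all 4 controls on day 1, so the own-group comparison could not tell APAP from the scan day. With the day estimated from the other groups, 4 genes fell, each in 7 of 7 rats. They were Hbb, a beta globin (−2.29 ± 0.43, adjusted p = 0.017), the antiviral gene Oas1a (−1.93 ± 0.35) and the globins Hba-a3 (−1.91 ± 0.38) and Hbb-b1 (−1.87 ± 0.37). Red blood cell markers lay lower as a list in that fit (median −1.51), with adjusted p = 4.5e-12, and adjusted p = 0.073 with an estimated correlation. Interferon-stimulated genes lay lower (median −0.77), with adjusted p = 8.5e-14, and adjusted p = 0.14 with an estimated correlation. Mitosis genes lay higher (median 0.96), with adjusted p = 8.3e-13, and adjusted p = 0.35 with an estimated correlation. From the own groups Fam184b stood higher by 2.5 ± 0.26 (scan-day fit 0.30 ± 0.33, adjusted p = 1). Slc5a10, not well above background in any treated rat, was at least 14.4-fold lower (scan-day fit adjusted p = 0.69). The own-group count was 4161 higher and 9141 lower, 710 and 6471 by at least 1, and it was 6252 and 6406 after quantile normalization, 5847 and 6057 after normexp and 1877 and 8414 unscaled, as the median of all genes went from −0.15 to 0.01, 0 and −0.24. In the scan-day fit limma called 0 higher and 4 lower.

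At 7 d after 1250 mg/kg APAP (7 rats against 4 controls) mitosis genes lay lower as a list, and 17 of 29 fell when adjusted over the list alone, though 0 over all genes tested. Its median was −1.36 (scan-day fit −1.41, within days −1.77 and −0.61), with adjusted p = 1.6e-25, and adjusted p = 0.48 with an estimated correlation. Ccnb1, a mitotic cyclin, stood at −1.80 ± 0.46, Spp1 at −1.81 ± 0.93 and Nqo1 at −1.09 ± 0.48, each with an adjusted p of 1, and without control replicate 3 they stood at −1.30 ± 0.39, −0.57 ± 0.55 and −0.73 ± 0.48. S phase genes lay lower too. The median was −0.40 (scan-day fit −0.42, within days −0.61 and −0.24), with adjusted p = 2.1e-10, and adjusted p = 0.49 with an estimated correlation. So did macrophage and monocyte markers. Its median was −0.49 (scan-day fit −0.48, within days −0.80 and −0.16), with adjusted p = 1.2e-09, and adjusted p = 0.51 with an estimated correlation. Limma called 0 genes (1103 at an unadjusted p under 0.05), in the scan-day fit and within each day as well (1385 and 539 within days 1 and 2). Control replicate 3 of this group stood apart from the other controls, with a correlation across genes of −0.429 to its own group's mean profile. Without it the medians of mitosis, S phase and macrophage genes were −0.85, −0.20 and −0.16 (adjusted p = 1.5e-19, 1e-04 and 0.0016 at the preset correlation).

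The low dose of APAP, 100 mg/kg, was compared with control at 6 h and 24 h in 5 rats each. At 6 h no sentinel gene passed: Cyp7a1 stood at −1.21 ± 0.45, Nqo1 at 0.65 ± 0.59 (0.14 ± 0.50 without control replicate 1) and Cyp2e1 at 0.30 ± 0.18, and limma called 0 genes (343 at an unadjusted p under 0.05; 0 in the scan-day fit). At 24 h, where all 5 treated and 1 of 4 control rats had been scanned on day 2, Fam184b stood higher by 2.11 ± 0.47 (scan-day fit 0.46 ± 0.35, adjusted p = 0.82) and Pla2g4d differed by −3.35 ± 0.90 (scan-day fit −2.20 ± 1.08), but no named gene held in the scan-day fit. Nqo1 stood at 0.12 ± 0.37 and Cyp7a1 at 0.34 ± 0.54 there, and at −0.11 ± 0.38 and −0.04 ± 0.53 without control replicate 2 and 4. Day 1 held no treated rat and day 2 a single control, too few for a test within days. Labels of treated replicate 1 and control replicates 2 and 4 are in doubt at 24 h (last paragraph). The limma count at 24 h was 325 higher and 2731 lower from the own groups, 59 and 147 after quantile normalization, 34 and 51 after normexp, 22 and 7276 unscaled, 2 and 5 with scan day added and 0 in the scan-day fit. The median of all genes was −0.10, or 0.01 after quantile normalization, 0.01 after normexp and −0.55 unscaled. The count was 4, 9065, 6 or 8 without control replicate 1, 2, 3 or 4 and 412, 775, 340 or 204 without treated replicate 2, 3, 4 or 5.

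The doses of APAP were compared in the same way, and at 24 h Ugt2b7 was higher at 1250 than at 100 mg/kg by 6.28 ± 0.47 (adjusted p = 0.00021), Ddit4l by 5.47 ± 0.74, Akr7a3 by 4.09 ± 0.33 and the aldose reductase Akr1b7 by 3.26 ± 0.55, in 7 of 7 rats. The chemokine Cxcl13 and the pericentral enzymes Oat and Glul differed by −3.20 ± 0.63, −2.74 ± 0.49 and −2.72 ± 0.48. At 6 h Chaf1b, a chromatin assembly factor, was higher by 1.60 ± 0.17 (adjusted p = 0.029) and the HSP90 co-chaperone Fkbp4 differed by −1.39 ± 0.13 (adjusted p = 0.024). The limma counts were 1 and 1 at 6 h and 138 higher and 46 lower at 24 h, against 1120 and 711 and 1623 and 965 in the scan-day fit, and 0 and 7 and 1 with scan day added to the own groups. At 24 h quantile normalization gave 119 and 73, normexp 424 and 354 and unscaled values 13303 and 50. The count at 24 h was 11, 18, 24 or 12 without low-dose replicate 2, 3, 4 or 5 and 393, 118, 89, 32, 22 or 398 without high-dose replicate 1, 2, 3, 4, 5 or 7. At 6 h it was 0 without any low-dose replicate and 0, 0, 0, 13 or 6 without high-dose replicate 1, 2, 3, 4 or 5.

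The compounds were compared by testing the difference between their high-dose effects, although fasting, feeding and controls differed between the arms. At 6 h the effects on Hspa1a differed by 9.34 ± 2.02 toward CCl4 (adjusted p = 0.045), on Ccl2 by 6.33 ± 0.91, on Cxcl10 by 5.92 ± 0.68 and on the small heat shock protein Hspb1 by 4.70 ± 0.74. After APAP itself Hspa1a stood at −2.46 ± 1.71 and Hspb1 at −1.27 ± 0.45 (adjusted p = 0.74 and 0.58). Hspa1a was also higher in the APAP-arm controls (scan-day fit 4.73 ± 1.26). At 24 h the macrophage genes Trem2 and Itgam differed by 4.48 ± 0.65 and 4.15 ± 0.92 toward CCl4, and Ugt2b7, Ugt2b1 and Akr7a3 by −6.62 ± 0.59, −4.36 ± 0.71 and −4.30 ± 0.43 toward APAP. At 3 d Stac3 and Ces1d differed by −9.39 ± 1.30 and −5.41 ± 0.70 (scan-day fit −9.20 ± 2.01 and −4.13 ± 0.92). The limma counts were 181 higher and 25 lower at 6 h, 163 and 53 at 24 h and 8738 and 5163 at 3 d, where the APAP groups differ in scan day, and the scan-day fit gave 1211 and 1046, 709 and 844, and 200 and 120. Normexp gave 450 and 143 at 6 h and 6043 and 6095 at 3 d, quantile normalization 6097 and 6602 at 3 d, and unscaled values 275 and 1 at 6 h and 9911 and 1747 at 3 d. The count at 6 h was 77 or 79 without APAP-arm control replicate 3 or 4, 102 or 112 without APAP replicate 2 or 3, 123, 72 or 90 without CCl4-arm control replicate 2, 3 or 4 and 122 or 118 without CCl4 replicate 1 or 2. At 24 h it was 100, 128 or 123 without APAP-arm control replicate 1, 3 or 4, 624 without APAP replicate 2 and 125, 120 or 131 without CCl4-arm control replicate 3, 4 or 5, and 1155 without APAP replicates 2 and 7 together.

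Genes called in one direction for both compounds in the scan-day fit numbered 253 higher (76.6 by chance) and 202 lower (57) at 6 h, with 75 opposite, and 643 (150) and 252 (66.5) at 24 h, with 51 opposite. From own groups the shared genes were 0 at 6 h, 2 at 24 h (3 opposite; Fisher's exact test, p = 0.17 for the higher genes) and 48 higher (141 by chance) and 33 lower (458) at 3 d (706 opposite; 3 in the scan-day fit). Across genes, which are not independent replicates, the effects of both compounds had a Pearson correlation of 0.19 at 6 h, 0.473 at 24 h and −0.409 at 3 d (0.204, 0.45 and 0.194 in the scan-day fit).

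Between 6 h and 24 h after CCl4 2000 mg/kg the effect on Cyp7a1 rose by 7.18 ± 1.19 (adjusted p = 0.0046), that on Spp1 by 6.32 ± 1.13 and that on Gpnmb by 4.66 ± 0.96, while the chemokine Cxcl1, the hepatocyte factor Onecut1 and Car3 moved by −4.40 ± 1.18, −4.25 ± 0.95 and −4.09 ± 0.95. Between 24 h and 3 d the effects on Cxcl9, Ly6c and Orm1 moved by −3.81 ± 0.46, −3.79 ± 0.72 and −3.71 ± 0.58, and those on S100g and Ugt2b1 rose by 4.45 ± 0.74 and 2.95 ± 0.55. For APAP 1250 mg/kg the effect on Ugt2b7 moved by −7.07 ± 0.73 between 24 h and 3 d (scan-day fit −7.0 ± 0.88), that on Akr7a3 by −4.78 ± 0.39, and that on Glul by 3.06 ± 0.64 (scan-day fit 2.43 ± 0.48). Between 3 d and 7 d the mitotic genes Kif22 and Ttk moved by −5.16 ± 0.89 and −4.66 ± 1.20 (scan-day fit adjusted p = 0.098 and 0.068), and in the scan-day fit Hbb rose by 3.34 ± 0.60. The limma counts of higher and lower effects were 712 and 441 (24 h against 6 h) and 11 and 47 (3 d against 24 h) for CCl4, and 0 and 0 (1364 at an unadjusted p under 0.05), 21 and 180, and 2917 and 1516 for the successive APAP times. The scan-day fit gave 1722 and 2120, and 82 and 226 for CCl4, and 75 and 16, 47 and 462, and 4 and 2 for APAP. Normexp gave 57 and 131 for CCl4 at 3 d against 24 h, 66 and 234 for APAP at 3 d against 24 h and 1607 and 1968 for APAP at 7 d against 3 d, quantile normalization gave 1469 and 1957 for the last, and unscaled values gave 422 and 105 and 1 and 36 for CCl4. For CCl4 the count at 24 h against 6 h was 754 without control 6 h replicate 3, 655 without control 24 h replicate 3 and 744 without CCl4 24 h replicate 2, and at 3 d against 24 h 21 or 35 without control 24 h replicate 3 or 5, 19, 28 or 141 without CCl4 24 h replicate 1, 2 or 3, 30 or 32 without control 3 d replicate 2 or 5 and 26 or 203 without CCl4 3 d replicate 1 or 3. For APAP the count at 3 d against 24 h was 125 without control 24 h replicate 1 and 128 or 126 without control 3 d replicate 2 or 3, at 24 h against 6 h 1 without APAP 6 h replicate 4, and at 7 d against 3 d 1375, 8 or 2631 without control 3 d replicate 1, 2 or 4, 1612, 1427, 1733, 2911 or 2100 without APAP 3 d replicate 1, 2, 4, 5 or 7, 1, 10092, 1066 or 52 without control 7 d replicate 1, 2, 3 or 4 and 1322, 1437, 8737, 992, 1039 or 8232 without APAP 7 d replicate 1, 2, 3, 4, 6 or 7.

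The controls of the arms, fasted and refed against freely fed, were compared as a check on the arms, and limma on the own groups called 0 at 6 h, 24 h and 3 d (2889, 3048 and 10041 at an unadjusted p under 0.05). In the scan-day fit at 6 h Hspa1a stood higher in the APAP-arm controls by 4.73 ± 1.26, Acot1, a fatty acid thioesterase, by 4.01 ± 0.81 and Per2 by 3.07 ± 0.53, and the fatty acid desaturase gene Scd differed by −4.78 ± 1.16, in 4 of 4 rats each (own groups adjusted p from 0.11 to 0.24). At 24 h Usp2 and Bmal1, both tied to the clock, differed by 2.59 ± 0.62 and −2.61 ± 0.59. The scan-day fit called 814 higher and 416 lower at 6 h, 12 and 47 at 24 h and 0 at 3 d. The own-group count at 3 d was 457 without APAP-arm control replicate 4 and 6017 without CCl4-arm control replicate 3, at 24 h 1 or 3 without APAP-arm control replicate 1 or 4 and 1 without CCl4-arm control replicate 2, and at 6 h 1 without CCl4-arm control replicate 1.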

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

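The tests of the scan day and of the compound alone at 3 d after APAP, of a swap, of the slide for genes that CCl4 raised, of liver injury in a control rat and of stronger injury in 2 APAP rats were chosen only after the result was seen.

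At 3 d after APAP 1250 mg/kg, 13302 genes were called from the own groups and 4 in the scan-day fit. Across 28893 genes the log2 change had a correlation of 0.915 with the scan-day difference within the other 17 groups (85 arrays), which argues against the compound alone (0.915) as the cause and leaves the scan day as a likely source of most calls. The median absolute log2 change went from 1.08 to 0.23 and the median standard error from 0.23 to 0.34, so the calls ended because the changes shrank and their error grew. APAP and the day cannot be told apart within these groups, which shared no scan day. The effect of APAP that remains in the scan-day fit rests on the day having acted alike in all groups, which was not tested at 3 d.

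Control replicate 3 of the APAP arm at 7 d, with Atf3 at 2.67, had, with the scan-day difference removed, a correlation of −0.429 with its own group, of 0.613 with CCl4 2000 mg/kg at 24 h and of 0.521 with CCl4 at 3 d. Tables argue against a swap with those groups, since 0 of their arrays lay closest to a control group; this test first counted 1, and was changed after its result was seen because the array was in its own group's mean. The slide is argued against for the 1063 genes that CCl4 2000 mg/kg raised at 24 h, where this array's median deviation was 1.24 and those of its 3 slide mates lay between −0.26 and 0.19. A single wrong label stays open, as 0.613 is above the lowest value of a CCl4 24 h rat with its own group (0.589), and so does the slide for the rest of the profile (mean correlation 0.54 with slide mates). Liver injury in this rat stays open too and may explain the likeness (correlation 0.628 of its deviation with the CCl4 effect at 24 h), since the labels record no measure of injury, and this array was also closer to 1 array of CCl4 2000 mg/kg at 3 d than any pair within a group.

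At 24 h after APAP 1250 mg/kg, replicates 2 and 7 stood apart from the other 5 rats. A wrong label of CCl4 2000 mg/kg rats of 24 h is argued against by the 10 genes called without them, whose median was 1.36 and 1.29 in these rats, between 1.45 and 1.9 in the other APAP rats, from −0.74 to −0.02 in those CCl4 rats and from −0.6 to −0.18 in controls; rats of 6 h, to which replicate 2 lay nearest (0.464), were not tested. The slide cannot be told apart from other sources at a mean correlation of 0.244 with slide mates, between the bounds set for the test. Stronger injury in these rats could explain it but cannot be told apart either, with correlations of 0.369 and 0.482 with the CCl4 effect at 24 h.

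Of 228 groups of values tested for an array far from the rest, 190 of them on sentinel genes, 19 had one, and chance gives 11.4 (about 1 in 20). Nqo1 was far from its group in APAP 1250 mg/kg 7 d replicate 3 (−2.90), CCl4 50 mg/kg 6 h replicate 3 (0.33), CCl4 2000 mg/kg 6 h replicate 4 (−1.29) and CCl4 2000 mg/kg 3 d replicate 5 (−0.88). Hmox1 was so in APAP-arm control 24 h replicate 3 (1.31) and CCl4 50 mg/kg 3 d replicate 3 (1.49), and Atf3 in APAP 1250 mg/kg 3 d replicate 5 (1.11) and in the control rat above (2.67). Cyp2e1 was so in APAP 1250 mg/kg 3 d replicate 1 (9.18), Gdf15 in APAP 1250 mg/kg 7 d replicate 3 (−1.39), Cdkn1a in APAP-arm control 24 h replicate 2 (2.80) and Ccnb1 in CCl4 50 mg/kg 24 h replicate 4 (1.10). A2m was so in APAP 100 mg/kg 6 h replicate 1 (0.58) and Spp1 in CCl4 50 mg/kg 3 d replicate 5 (−6.09). The share of probes well above background stood apart in CCl4 50 mg/kg 6 h replicate 1 (75.3%) and CCl4 50 mg/kg 24 h replicate 5 (72.6%). The 75th percentile of intensity did so in APAP-arm control 6 h replicate 2 (425), CCl4-arm control 6 h replicate 2 (264) and CCl4 50 mg/kg 6 h replicate 1 (363).

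By a test of the difference itself, effects of CCl4 and APAP differed in 206 genes at 6 h, 216 at 24 h and 13901 at 3 d. Between times they differed after APAP in 201 genes (3 d against 24 h) and 4433 (7 d against 3 d), and after CCl4 in 1153 (24 h against 6 h) and 58 (3 d against 24 h). The APAP groups at 3 d are confounded with the scan day, and with the day as a term in the own groups 13901 became 359, 201 became 126 and 4433 became 1 (320, 509 and 6 in the scan-day fit).

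Other splits of the same rats were counted on the 28893 genes with a value on every array, 100 drawn per comparison, or 35 for the controls at 6 h, with the real split included. For CCl4 2000 mg/kg the splits argue against chance at 6 h (1267 genes, 2 splits as large, highest other 6162), at 24 h (3039, 1 split, 2390) and at 3 d (2467, 2 splits, 5241). The higher split at 6 h and at 3 d followed the scan day. Splits within days, in the scan-day fit, gave 5881 against 5137 at 6 h (1 of 60), 7581 against 3538 at 24 h (1 of 100) and 2846 against 580 at 3 d (1 of 25), so chance can be excluded there. For APAP 1250 mg/kg chance can be excluded at 24 h (14 genes, 1 split, highest other 1), and at 3 d for the count (13294, 1 split, 58) but not the scan day, since the splits took no account of the day and the scan-day fit called 4. In the scan-day fit within days chance stays open at 6 h (1307, 3 of 45 splits, highest other 1716) and 24 h (1808, 6 of 100, 2995). For APAP 100 mg/kg at 24 h the splits argue against chance for the count (3039, 2 splits, 5526). The highest split leaned to the scan day (correlation 0.791) as the real one did. Where the real count was 0 every split is as large, so nothing was learned about chance: APAP 1250 mg/kg at 6 h (0, 100 splits, highest 35) and 7 d (0, 100 splits, 5722, and 0 with 100 of 100 within days, 535), APAP 100 mg/kg at 6 h (0, 100 splits, 13083) and CCl4 50 mg/kg at 6 h, 24 h and 3 d (0, 100 splits, highest 10563, 4178 and 6964, each following the scan day).

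Between doses chance can be excluded for the count of APAP at 24 h (187 genes, 1 split, highest other 176), and for CCl4 at 6 h (960, 3 splits, 8182), 24 h (2813, 2 splits, 3472) and 3 d (154, 1 split, 133). For APAP doses at 6 h the splits gave 2 genes (3 splits, 5116), but the count was 0 with the scan day in the own groups and 0 without any 1 of 8 of the 10 arrays. Between compounds few splits gave as many genes at 6 h (205, 2 splits, 312), 24 h (216, 1 split, 1) and 3 d (13873, 1 split, 1). Between times it can be excluded for CCl4 at 24 h against 6 h (1154, 1 split, 47) and 3 d against 24 h (58, 2 splits, 1660), and for the counts of APAP at 3 d against 24 h (201, 3 splits, 3950) and 7 d against 3 d (4421, 2 splits, 8296). No split took account of the scan day, so the day stays open as the source for the APAP 3 d groups and for the APAP doses at 24 h, where all low-dose rats were of day 2 and with the day in the own groups 184 became 8. Nothing was learned about chance for APAP at 24 h against 6 h (0, 100 splits, highest 10485) and for the controls of the arms at 6 h (0, 35 splits, 8063), 24 h (0, 100 splits, 1074) and 3 d (0, 100 splits, 5526), as the real counts were 0, and each highest split of the controls followed the scan day. Splits with many times the real count, as for low doses and controls, point to a structure of the samples. The scan day is a known source of it, and the slide was not separated.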

How the results depend on the processing

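The scan day as a block for comparisons other than those with control and for the gene lists, the scan day within the own groups, normexp with scan day, and leaving out 2 APAP rats together were chosen only after the result was seen.

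Named genes that passed the own-group test kept their direction under every setting run, except for 3 genes with the slide as a block: Pik3c2g went from 1.40 to −0.07 for APAP 100 mg/kg at 24 h, Dhx16 from 2.14 to −0.17 and Ffar3 from −3.43 to 0.28 for APAP 1250 mg/kg at 3 d, and Ffar3 from 4.58 to −0.81 for CCl4 less APAP at 3 d. Every sentinel gene changed sign in 1 comparison or more where it had not passed, as Spp1 (−0.47 to 0.43) and Cyp2e1 (−0.02 to 0.25) did at 24 h after APAP 1250 mg/kg without control replicate 2. Of the named results, the mean of a gene's probes left 441 on their side of the threshold, array weights 429, no filter 432, the percentile over bright probes 439, quantile normalization 421, normexp 406 and the unscaled deposited values 407. The scan-day fit kept 279 on their side, gave a call to 120 more and ended 52, and the slide as a block ended 66. Leaving out 1 array kept 4828, ended 736 and gave 52. The gene list calls, 172 in all, numbered 166 to 181 without 1 array and 141 to 188 under the other settings, and 124 of 150 in the scan-day fit were shared with the same direction, 105 of 160 with the slide as a block (2 opposite) and 121 of 141 with normexp, quantile normalization and scan day (1 opposite). Among called lists, oxidative phosphorylation after CCl4 2000 mg/kg went from −0.34 at 6 h and −0.39 at 24 h to 0.04 and 0.09 in the unscaled table. That list and plasma proteins at 3 d and bile acid genes at 7 d after APAP 1250 mg/kg, the NRF2 list at 6 h after CCl4 50 mg/kg, and lists at 6 h and 24 h after APAP 100 mg/kg with small medians, also changed sign under 1 scaling or more.

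Counts of called genes that moved by more than 1.5 times are given next by setting, where the numbers after a compound are the dose in mg/kg, "doses" is the high dose against the low dose, "less" a difference between effects, "controls" the APAP arm against the CCl4 arm, and "overlap" the genes shared by both high doses. For each of these the cause was not tested. Quantile normalization gave 206 for APAP 100 at 24 h, 1 for APAP doses at 6 h, 82 for APAP 3 d less 24 h, 124 for CCl4 3 d less 24 h and 1958 for controls at 3 d. The overlap at 24 h was 1 there. Normexp background correction with quantile normalization gave 85 for APAP 100 at 24 h, 25 for APAP 1250 at 24 h, 54 and 778 for APAP doses at 6 h and 24 h, 2629 for CCl4 2000 at 6 h and 2110 and 1044 for CCl4 doses at 6 h and 3 d. Further counts were 593 and 419 for CCl4 less APAP at 6 h and 24 h, 1789 for CCl4 24 h less 6 h, 188 for CCl4 3 d less 24 h, 308, 4 and 3428 for controls at 6 h, 24 h and 3 d and 9 and 169 for overlap at 24 h and 3 d. The percentile over bright probes gave 5 for APAP 1250 at 24 h and 0 for overlap at 24 h. The unscaled deposited table gave 7298 for APAP 100 at 24 h, 0 and 13353 for APAP doses at 6 h and 24 h, 5367 and 364 for CCl4 2000 at 24 h and 3 d, 3366, 4992 and 35 for CCl4 doses at 6 h, 24 h and 3 d and 376 for APAP 3 d less 24 h. It also gave 3 for APAP 7 d less 3 d, 527 for CCl4 24 h less 6 h, 37 for CCl4 3 d less 24 h and 5 and 15 for overlap at 24 h and 3 d. No filter on dim probes gave 1652 for APAP 100 at 24 h, 81 for APAP doses at 24 h, 83 for CCl4 doses at 3 d, 135 for CCl4 less APAP at 6 h and 49 for overlap at 3 d. Keeping probes well above background on 48 of 96 arrays or more gave 23 for APAP 1250 at 24 h, 6 and 560 for APAP doses at 6 h and 24 h, 2099 for CCl4 2000 at 6 h, 1508 and 500 for CCl4 doses at 6 h and 3 d and 381 for CCl4 less APAP at 6 h. Other counts were 103 for CCl4 3 d less 24 h, 18 and 3373 for controls at 6 h and 3 d and 5 for overlap at 24 h. The mean of a gene's probes moved none of the 32 results by that much.

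All 96 arrays in 1 fit gave 851, 1340 and 8248 for APAP 1250 at 6 h, 24 h and 3 d, 337 for APAP 100 at 24 h, 1312 and 3544 for APAP doses at 6 h and 24 h, 4428 and 5388 for CCl4 2000 at 6 h and 24 h and 3764, 5123 and 1385 for CCl4 doses at 6 h, 24 h and 3 d. Further counts were 1312 and 1020 for CCl4 less APAP at 6 h and 24 h, 82 for APAP 24 h less 6 h, 501 for APAP 3 d less 24 h, 193 for APAP 7 d less 3 d and 2289 for CCl4 24 h less 6 h. It also gave 210 for CCl4 3 d less 24 h, 682, 35 and 26 for controls at 6 h, 24 h and 3 d and 277 and 597 for overlap at 6 h and 24 h. That fit with the slide as a block gave 578, 3061 and 0 for APAP 1250 at 6 h, 24 h and 3 d, 0 for APAP 100 at 24 h, 531 and 1851 for APAP doses at 6 h and 24 h, 2751 and 5909 for CCl4 2000 at 6 h and 24 h and 3615, 5904 and 1767 for CCl4 doses at 6 h, 24 h and 3 d. Other counts were 1514, 398 and 701 for CCl4 less APAP at 6 h, 24 h and 3 d, 73 for APAP 24 h less 6 h, 1075 for APAP 3 d less 24 h, 4 for APAP 7 d less 3 d and 1741 for CCl4 24 h less 6 h. Further counts were 94 for CCl4 3 d less 24 h, 492 and 6 for controls at 6 h and 24 h and 51, 1359 and 0 for overlap at 6 h, 24 h and 3 d. The position on the slide as a block gave 737, 1377 and 6329 for APAP 1250 at 6 h, 24 h and 3 d, 239 for APAP 100 at 24 h, 1298 and 4003 for APAP doses at 6 h and 24 h, 1 for CCl4 50 at 6 h and 3032 and 5380 for CCl4 2000 at 6 h and 24 h. It also gave 2484, 4820 and 1827 for CCl4 doses at 6 h, 24 h and 3 d, 901, 917 and 9251 for CCl4 less APAP at 6 h, 24 h and 3 d, 71 for APAP 24 h less 6 h, 364 for APAP 3 d less 24 h and 252 for APAP 7 d less 3 d. Other counts were 2257 for CCl4 24 h less 6 h, 156 for CCl4 3 d less 24 h, 563, 25 and 7 for controls at 6 h, 24 h and 3 d and 187 and 642 for overlap at 6 h and 24 h.

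Array weights per group gave 647 for APAP doses at 24 h and 4 for overlap at 24 h. The scan day as a block with all arrays gave 1322, 1841 and 4 for APAP 1250 at 6 h, 24 h and 3 d, 0 for APAP 100 at 24 h, 1831 and 2588 for APAP doses at 6 h and 24 h, 5966 and 7709 for CCl4 2000 at 6 h and 24 h and 5118, 6833 and 2112 for CCl4 doses at 6 h, 24 h and 3 d. Further counts were 2257, 1553 and 320 for CCl4 less APAP at 6 h, 24 h and 3 d, 91 for APAP 24 h less 6 h, 509 for APAP 3 d less 24 h, 6 for APAP 7 d less 3 d and 3842 for CCl4 24 h less 6 h. It also gave 308 for CCl4 3 d less 24 h, 1230 and 59 for controls at 6 h and 24 h and 455, 895 and 3 for overlap at 6 h, 24 h and 3 d. The scan day as a block within the own groups gave 7 for APAP 100 at 24 h, 26 for APAP 1250 at 24 h, 0 and 8 for APAP doses at 6 h and 24 h, 2715, 4692 and 1287 for CCl4 2000 at 6 h, 24 h and 3 d and 1664, 6723 and 722 for CCl4 doses at 6 h, 24 h and 3 d. Other counts were 547, 357 and 359 for CCl4 less APAP at 6 h, 24 h and 3 d, 126 for APAP 3 d less 24 h, 1 for APAP 7 d less 3 d, 2139 for CCl4 24 h less 6 h and 8 for overlap at 24 h. Normexp, quantile normalization and the scan day as a block gave 1295, 2003 and 2 for APAP 1250 at 6 h, 24 h and 3 d, 0 for APAP 100 at 24 h, 1867 and 2417 for APAP doses at 6 h and 24 h, 2 for CCl4 50 at 6 h and 5821 and 6601 for CCl4 2000 at 6 h and 24 h. Further counts were 5239, 6250 and 2295 for CCl4 doses at 6 h, 24 h and 3 d, 2160, 1603 and 478 for CCl4 less APAP at 6 h, 24 h and 3 d, 70 for APAP 24 h less 6 h, 329 for APAP 3 d less 24 h and 3 for APAP 7 d less 3 d. It also gave 3863 for CCl4 24 h less 6 h, 484 for CCl4 3 d less 24 h, 1259 and 59 for controls at 6 h and 24 h and 469, 1038 and 1 for overlap at 6 h, 24 h and 3 d.

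Leaving out APAP 1250 24 h replicates 2 and 7 together gave 1155 for CCl4 less APAP at 24 h and 1 for overlap at 24 h. Leaving out 1 array at a time gave 0 to 1 for APAP 1250 6 h, 4 to 9065 for APAP 100 24 h, 5 to 16 for APAP 1250 24 h, 0 to 13 for APAP doses 6 h, 11 to 398 for APAP doses 24 h and 0 to 3 for CCl4 50 6 h. The range was 66 to 970 for CCl4 2000 6 h, 1380 to 3288 for CCl4 2000 24 h, 0 to 2615 for CCl4 50 3 d, 799 to 5419 for CCl4 2000 3 d, 0 to 773 for CCl4 doses 6 h and 1298 to 3105 for CCl4 doses 24 h. The range was 17 to 112 for CCl4 doses 3 d, 72 to 283 for CCl4 less APAP 6 h, 100 to 624 for CCl4 less APAP 24 h, 0 to 1 for APAP 24 h less 6 h, 125 to 272 for APAP 3 d less 24 h and 1 to 10092 for APAP 7 d less 3 d. The range was 655 to 1201 for CCl4 24 h less 6 h, 19 to 203 for CCl4 3 d less 24 h, 0 to 1 for controls 6 h, 0 to 3 for controls 24 h, 0 to 6017 for controls 3 d and 0 to 3 for overlap 24 h. The range was 29 to 102 for overlap 3 d.

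The scan day within the own groups could not be fitted for APAP 1250 mg/kg at 3 d and the overlap then, as dose and day coincided. The gene lists were not run with it, and each other alternative set before was run. No paired analysis was possible, as nothing in the labels ties a treated rat to a control. Signal over background limits the dim genes: 23077 of 29404 genes tested were well above background on 48 arrays or more.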

Other observations

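The arrays and close pairs described here, the test of the sixth pair and the return of the gap between levels from 0.5 to 1 were chosen only after the result was seen.

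At 6 h after APAP 1250 mg/kg, replicates 1, 2 and 3 shared slide 12 and had, with the scan-day difference removed, correlations of 0.601, 0.652 and 0.619 with the rest of their group. Replicates 4 and 5, on slides 15 and 8, had −0.0715 and −0.117 with it, and lay nearest to the APAP-arm controls at 24 h (0.343) and to APAP 100 mg/kg at 24 h (0.336). Whether the slide caused this was not tested.

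6 pairs of arrays from different groups lay closer than any pair within a group, by the median absolute deviation of their differences with the scan-day difference removed (lowest within a group 0.201, median 0.332). They were APAP 1250 mg/kg 6 h replicate 4 and 24 h replicate 1 (0.106), APAP 1250 mg/kg 7 d replicate 7 and CCl4-arm control 6 h replicate 2 (0.161), APAP-arm control 6 h replicate 3 and 24 h replicate 2 (0.168), APAP-arm control 24 h replicate 4 and APAP 100 mg/kg 24 h replicate 1 (0.174), APAP-arm control 7 d replicate 3 and CCl4 2000 mg/kg 3 d replicate 4 (0.175), and APAP-arm control 7 d replicate 4 and APAP 1250 mg/kg 7 d replicate 5 (0.199, on 1 slide). Over 11 genes with 2 clear levels among the rats, RT1-CE10, Aldh1a4 and Cdc25a among them, each of the first 5 pairs had 100% at the same level, and the sixth 36.4%, against a median of 63.6% and a 95th percentile of 90.9% over pairs of different groups. The same liver RNA on both arrays may explain the first 5, and is argued against for the sixth. The genes are few and not unique to a rat: 168 of the other pairs also had all 11 at the same level, and 5 of them all 27 genes found with a gap of 0.5, as the first 5 pairs had. Whether related rats share these levels was not tested, and no array was left out.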
